A study of Homo sapiens with 12 samples.

How the data were processed

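RNA was measured by sequencing in DLD1 cells, an established human colorectal adenocarcinoma line, in 4 groups of 3 libraries: medium with 10% fetal bovine serum (FBS), medium with lipoprotein-deficient serum (LPDS), and LPDS with either 3 µM fenretinide or 3 µM ivermectin for 24 h. The percentage of LPDS in the medium is not given in the sources used here. Groups and replicate numbers were taken from the sample titles. The titles name no vehicle or treatment time for the LPDS group, so a drug cannot be told apart from its solvent or handling. Nothing in the labels says that the 3 libraries of a group came from separate cultures, so the p-values measure only the spread between these libraries, which may be technical. Replicate libraries differed by more than counting noise (chi-square per gene of 7.91 to 39.8 over the pairs), so each was counted as a separate library.

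The expression table, although named for TPM, held log2 CPM (counts relative to library size) as deposited by the authors. It had 13517 genes and values below 0 that ended at a shared floor of -4.43. The average column of the authors' deposited comparison tables equalled these values recomputed with an offset of 0.5 counts to within 1.18e-06, which fixes a prior count of 2 in the expression table and gives the effective library sizes. These ran from 35856474 to 48097451, and the recovered estimated counts summed to 35084855 to 49122965 per library. At 1 CPM the smallest library holds 35.9 estimated counts, a counting error of 16.7%. Recovered counts were not whole numbers (2.01% lay within 0.01 of one, the share chance gives). The reads were quantified with kallisto and processed with edgeR on hg38, per the submitters' processing notes, and versions are not given in the sources used here. The authors' deposited tables for 3 comparisons gave log2 fold changes, p-values and adjusted p-values, under column names that limma's result tables use, per the file headers. The medium table was signed FBS minus LPDS and was turned to LPDS minus FBS here.

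The design written before the data were examined assumed TPM and a test on log2(TPM + 1) of genes with at least 1 in at least 3 libraries. Because the table held log2 CPM, the test was run on the values as deposited. That scale was chosen from the unit of the values before any test was run, and it was reconsidered and kept once the counts on both scales were known. On the scale of the written design, log2(CPM + 1), the numbers of genes called were 1317 for medium, 3133 for fenretinide, 7410 for ivermectin and 6710 for fenretinide against ivermectin, beside 1320, 3141, 7370 and 6692 on the deposited values. Log2 fold changes depend on the offset and understate the change of low genes when it is large. Every listed gene reached 1 CPM in at least 3 libraries, so the filter removed 0 genes. CPM values in the text have the floor subtracted.

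Genes were tested with limma 3.58.1 in R 4.3.3 (eBayes with a trend, two-sided) in one fit of 12 libraries with 4 group means, and p-values were adjusted by Benjamini-Hochberg over 13517 genes at a threshold of 0.05. Every adjusted p in the text comes from limma. Before the data were examined 26 gene lists were fixed, covering lipid metabolism, stress responses, mitochondria, cell cycle, inflammation, intestinal identity, ribosomal proteins and markers of other cell types. They were tested with limma's camera at a preset correlation of 0.01 between genes, adjusted over the 26 lists within a comparison, and again with an estimated correlation and with fry. In simulated libraries with 200 changed genes among 13517, the fit recovered 81%, 79%, 77% and 76% of 1.5-fold changes and 93%, 90%, 93% and 92% of 2-fold changes in the medium, fenretinide, ivermectin and drug-against-drug comparisons. Unchanged genes made up 5.05%, 4.17%, 7.07% and 4.76% of the calls in these simulations. In each of them camera called the 1 list that was moved and 0 of the 25 others. The simulated genes varied independently, whereas the estimated correlation in the real lists reached 0.894 (mitochondrially encoded). These simulations therefore do not test the list calls where genes of a list vary together. Beside the moved list, the changed genes were drawn only from genes above 2 CPM in LPDS, and every simulated group had the same spread. In the real data the chi-square per gene was 7.91 to 13.0 within FBS and LPDS and 21.3 to 39.8 within the drug groups. Recovery of lower genes and false calls under an unequal spread were therefore not tested.

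Genes named in the text follow a rule fixed before the data were examined. In each comparison these were the 6 largest rises and 6 largest falls among genes with an adjusted p under 0.05, a mean of at least 5 in the higher group (written for TPM, applied to CPM), no overlap between the replicates of the groups, and a symbol that is not a LOC, LINC, AC, AL or AP clone or antisense name. To these were added the 3 members with the smallest p of each of the 6 leading gene lists, and, whatever their values, a fixed set that includes INSIG1, SCD, ABCA1, DEGS1, DDIT3 and CDKN1A. From a list that did not pass, its 2 members with the smallest p could be named. Some genes that the rule selects are not reported here.

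Overlaps between comparisons that share the LPDS libraries were set beside 100 simulations of unchanged groups and beside the overlap of independent lists; 3 LPDS libraries cannot be split into parts of 2. Alternatives fixed before the data were examined were offsets of 0.1 and 5, no filter, a mean of at least 5 CPM, median-of-ratios scaling, quantile normalization, a fit of only the compared groups, a replicate block, robust eBayes, limma treat against a fold change of 1.2, and leaving out each library. The log2(CPM + 1) scale, limma voom on the recovered counts, each drug group against FBS, and list counts without each library were added after seeing the data. Gene positions are from GENCODE 29 on GRCh38. Of the gene names, 23 had been turned into dates and 4 entries shared a name; these were tested but are not named. Genes with near-identical copies, such as AKR1C1 and AKR1C2, HSPA1A and HSPA1B, or PRSS1 and PRSS2, share reads, so their separate values are uncertain.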

Results

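Gene expression was measured in 12 libraries of DLD1 colorectal adenocarcinoma cells, 3 in each of 4 groups. Cells grew in 10% FBS or in LPDS, a serum from which lipoproteins have been removed, and LPDS cultures also received fenretinide, a synthetic retinoid, or ivermectin, an antiparasitic drug, each at 3 µM for 24 h. Effective library sizes ran from 35856474 to 48097451, and 13517 genes were tested. The series asks, by its title, how restricting lipids in the medium changes the sensitivity of cancer cells, and the comparisons set LPDS against FBS, each drug against LPDS, and the drugs against each other. Values are CPM with the SD over 3 libraries, and fold changes are on the log2 CPM scale with the SE of the fit.

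Genes of sterol and fatty acid synthesis were higher in LPDS than in FBS. SCD, the stearoyl-CoA desaturase (chromosome 10, 100347124 to 100364834), rose from 454 ± 36.8 CPM in FBS to 1418 ± 37.4 CPM in LPDS (log2 fold change 1.65, SE 0.102, adjusted p = 8.32e-07). INSIG1, a sterol-regulated protein that retains SCAP in the ER (chromosome 7, 155297776 to 155310235), rose from 78.4 ± 15.5 to 237 ± 10.6 CPM. HMGCS1, an enzyme of the mevalonate pathway, rose from 206 ± 18.1 to 472 ± 10.4 CPM, and DHCR7 and FDPS by 0.96 and 0.68 on the log2 scale. ABCA1, DEGS1, DDIT3 and CDKN1A did not pass (adjusted p = 0.219, 0.980, 0.300 and 0.102). CDKN1A passed with only FBS and LPDS fitted (log2 fold change -0.27, adjusted p = 0.0384, range over the alternatives 0.0384 to 1). That range includes the test against a 1.2-fold change, which asks for more than a difference from 0.

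Of 21 cholesterol biosynthesis genes, 18 rose, 0 fell and 3 did not pass (19 rose adjusted over the list alone), with a median log2 fold change of 0.68 and a camera adjusted p of 1.55e-23. Sterol uptake and sensing genes rose in 8 of 13, among them STARD4, and 5 did not pass (8 adjusted over the list alone, camera adjusted p = 2.28e-09). Fatty acid synthesis and desaturation genes rose in 9 of 19 (10 adjusted over the list alone, camera adjusted p = 7.65e-06), with SREBF1 at 0.92 and FASN at 0.56. These 3 lists also passed with an estimated correlation (adjusted p = 0.00869, 0.0114 and 0.00869).

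Inflammatory and interferon-induced genes were lower in LPDS. NF-kB and chemokine genes fell in 8 of 13, 0 rose and 5 did not pass (10 fell adjusted over the list alone), with CXCL1 going from 131 ± 5.10 to 69.3 ± 4.28 CPM and TNFAIP3 and CCL20 at -0.67 and -0.59. The list passed camera at an adjusted p of 1.76e-10 and at 0.00869 with an estimated correlation. Interferon response genes fell in 8 of 14 (9 adjusted over the list alone, where 1 rose), led by IFI44, which went from 13.3 ± 1.63 to 1.47 ± 0.222 CPM, and by DDX58 and IFIT1 at -1.34 and -1.32. That list had a camera adjusted p of 1.79e-08, and adjusted p = 0.0652 with an estimated correlation. Wnt target and intestinal stem cell genes fell in 8 of 14 (9 adjusted over the list alone), with LEF1 at -0.51, ZNRF3 at -0.27 and EPHB3 at -0.41. The camera adjusted p was 3.68e-06, and adjusted p = 0.0869 with an estimated correlation. The 8 members that fell became 4 without FBS replicate 2 or 3 or LPDS replicate 1 or 3, and 5 without LPDS replicate 2.

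Among the largest rises were IKZF3, TLE2, KCNK4-TEX40, TMPRSS4 and CTHRC1. TLE2 rose from 2.16 ± 0.189 to 13.2 ± 0.701 CPM (log2 fold change 2.59, adjusted p = 6.39e-08). The largest falls belonged to PTGS2, IFI44, CCL5, KLF2, TNFRSF11B and DAPP1, and PTGS2 went from 7.01 ± 0.666 to 0.573 ± 0.0195 CPM.

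In the limma fit 1320 of 13517 genes passed, 764 higher and 556 lower in LPDS. Another 3 lists passed camera: 5 ATF4 and integrated stress response genes rose and 2 fell of 29 (8 rose and 2 fell adjusted over the list alone), 6 NRF2 targets rose and 1 fell of 18 (7 rose and 1 fell adjusted over the list alone), and 1 ribosomal protein gene rose of 20 (1 adjusted over the list alone). None of these 3 held with an estimated correlation, at adjusted p = 0.406, adjusted p = 0.0869 and adjusted p = 0.460. The integrated stress response list did not pass camera without FBS replicate 2 (adjusted p = 0.0741, range over the alternatives 0.000864 to 0.406). Its members that rose became 3 without FBS replicate 2 or 3 or LPDS replicate 2 or 3, and those that fell became 1 without FBS replicate 1 or 2 or any one LPDS library. The ribosomal protein list did not pass with fry (adjusted p = 0.0695, range 1.86e-05 to 0.460), and 0 of its members passed whichever library was left out. Fitting only FBS and LPDS gave 2062 genes and testing against a 1.2-fold change gave 300. The count was 863 without FBS replicate 2, 813 without FBS replicate 3 and 816 without LPDS replicate 3, with 496 and 484 higher without the latter 2 libraries. The number lower was 335, 317, 348 and 332 without FBS replicates 2 and 3 and LPDS replicates 1 and 3.

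**Figure D1:**
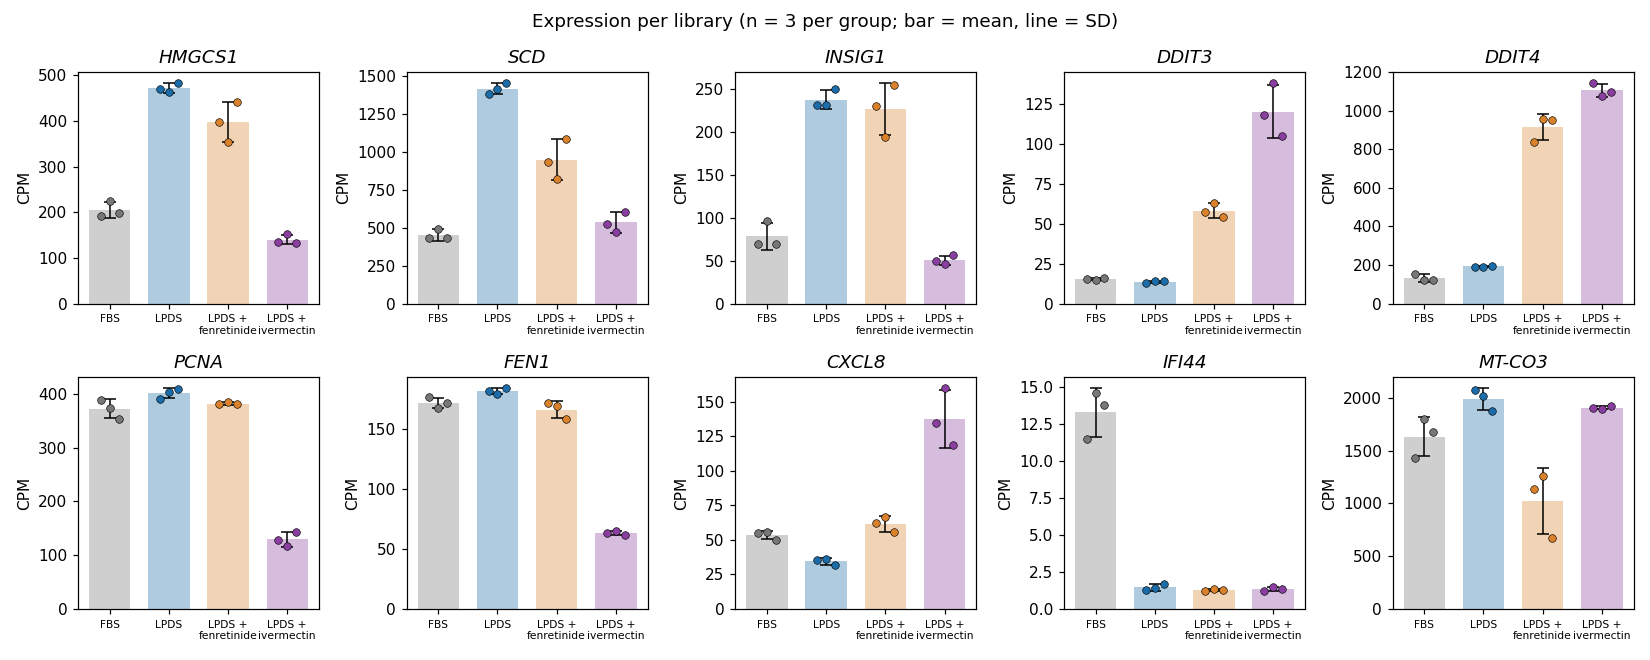
CPM of 10 genes in each of 12 libraries, by group on the x axis; points are libraries, bars the mean of 3 and lines the SD. HMGCS1, SCD and INSIG1 are higher in LPDS than in FBS and lower again with ivermectin.

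Fenretinide raised genes of the integrated stress response. DDIT4, an inhibitor of mTORC1 signalling (chromosome 10, 72273920 to 72276036), rose from 193 ± 2.45 CPM in LPDS to 915 ± 68.9 CPM (log2 fold change 2.24, SE 0.0818, adjusted p = 1.35e-08). DDIT3, which encodes the stress-induced transcription factor CHOP (chromosome 12, 57516588 to 57521737), rose from 13.8 ± 0.720 to 58.3 ± 4.48 CPM, and SESN2 by 1.45. The other largest rises were DUSP5, COL13A1, RP11-442H21.2 and HERPUD1, and the largest falls C2orf54, MYH7B, FGD2, TGFB3, CSPP1 and ASCL2. ASCL2, an intestinal stem cell transcription factor, went from 198 ± 20.8 to 81.9 ± 4.68 CPM. CDKN1A, the cyclin-dependent kinase inhibitor p21, rose by 0.87.

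Of 29 ATF4 and integrated stress response genes, 25 rose, 1 fell and 3 did not pass (26 rose adjusted over the list alone), with a camera adjusted p of 5.57e-23 and 0.00906 with an estimated correlation. Unfolded protein response genes rose in 15 of 20 (16 adjusted over the list alone), with HSPA5, the ER chaperone BiP, going from 495 ± 24.9 to 1067 ± 30.9 CPM and XBP1 rising by 0.57. The camera adjusted p was 4.09e-09, and adjusted p = 0.222 with an estimated correlation. Immediate early genes rose in 10 of 14 (12 adjusted over the list alone, where 1 fell, as 1 did without fenretinide replicate 2), with IER3 at 0.78, KLF6 at 0.68 and MYC at 0.37 (camera adjusted p = 1.47e-06, and adjusted p = 0.222 with an estimated correlation). Hypoxia and glycolysis genes rose in 9 of 16 (9 adjusted over the list alone), with NDRG1 at 1.24, VEGFA at 0.86 and SLC2A1 at 0.77, and passed at 3.97e-05 and at 0.0229 with an estimated correlation.

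Mitochondrially encoded genes fell in 5 of 13 (11 adjusted over the list alone), with a median of -0.51. MT-CO3 went from 1989 ± 103 to 1023 ± 309 CPM, and MT-ATP6 and MT-ATP8 were at -1.04 and -1.05. The share of counts from these genes was 1.77%, 1.85% and 1.04% in fenretinide replicates 1 to 3, against 2.29% ± 0.111 in LPDS. In FBS replicates 1 to 3 it was 1.92%, 2.45% and 2.36%. The camera adjusted p was 0.000113, and adjusted p = 0.366 with an estimated correlation. Without fenretinide replicate 3 the list median was -0.22 and 5 members were lower, and without fenretinide replicates 1 and 2 the numbers lower were 8 and 12. DNA replication genes fell in 8 of 20 (9 adjusted over the list alone), with MCM5 at -0.32, MCM3 at -0.34 and MCM7 at -0.15 (camera adjusted p = 0.000318, and adjusted p = 0.245 with an estimated correlation). The members that fell became 4, 3 and 4 without LPDS replicates 1, 2 and 3 and 4 without fenretinide replicate 2. MCM7 no longer passed without LPDS replicate 3 (adjusted p = 0.0656, range over the alternatives 0.0107 to 1). The upper end of that range came from the test against a 1.2-fold change. Mitosis genes did not pass with fenretinide, with 0 higher and 0 lower of 18, a median of 0.0084 and a camera adjusted p of 0.680.

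Cholesterol biosynthesis genes fell with fenretinide in 10 of 21 and 0 rose (10 fell and 2 rose adjusted over the list alone, camera adjusted p = 0.000635, and adjusted p = 0.222 with an estimated correlation). Without fenretinide replicate 2, 2 of them were higher. INSIG1, ABCA1 and DEGS1 did not pass (adjusted p = 0.705, 0.993 and 0.910), and SCD fell from 1418 ± 37.4 to 950 ± 134 CPM. The fatty acid synthesis list, with 6 of 19 genes lower and 1 higher (7 and 1 adjusted over the list alone), did not pass camera (adjusted p = 0.0812) but passed fry (adjusted p = 0.000423, range over the alternatives 0.000423 to 0.222). The gene higher no longer passed without any one LPDS library or fenretinide replicate 1 or 2. The 2 members with the smallest p were FASN and SREBF1, at 0.686 and 0.732 times the LPDS level. Nor did the retinoic acid response list pass camera, with 3 of 11 genes higher (5 adjusted over the list alone, camera adjusted p = 0.128), and with fry it passed (adjusted p = 0.002, range 0.002 to 0.222). DHRS3, a retinaldehyde reductase, and CYP26B1, a retinoic acid hydroxylase, had its smallest p, at 2.92 and 1.46 times the LPDS level.

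In all, 3141 genes passed, 1553 higher and 1588 lower. The number lower was 980 and 1005 without LPDS replicates 2 and 3. Further lists that passed camera but not with an estimated correlation were NRF2 targets (8 rose and 1 fell of 18, adjusted p = 0.130 with an estimated correlation), lysosome and autophagy (8 rose of 22, adjusted p = 0.0627), p53 targets (7 rose and 2 fell of 16, adjusted p = 0.114), NF-kB (4 rose and 1 fell of 13, adjusted p = 0.222), interferon response (4 fell of 14, adjusted p = 0.222), Wnt targets (2 rose and 9 fell of 14, adjusted p = 0.222) and the nuclear-encoded respiratory chain (3 fell of 26, adjusted p = 0.522). Adjusted over the list alone these counts were the same except that 3 lysosome genes and 3 p53 targets fell and 2 respiratory chain genes fell. The respiratory chain list did not pass with fry (adjusted p = 0.053, range over the alternatives 0.00478 to 0.522). NRF2 targets that rose became 5 without LPDS replicate 1, Wnt targets that rose became 1 without any one LPDS library or fenretinide replicate 1 or 2, the NF-kB gene that fell no longer passed without LPDS replicate 1 or 2 or fenretinide replicate 3, and 1 lysosome gene fell without fenretinide replicate 1. Against a 1.2-fold change 334 genes passed, and CSPP1 no longer passed without LPDS replicate 2 or 3 (adjusted p = 0.0572 and 0.0519, range 0.00822 to 0.140).

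Ivermectin changed 7370 of 13517 genes, with 3663 higher and 3707 lower. Its largest rises were SPRR2D, FAM129A, DDIT3, NUPR1, ADM2 and SLC16A4, and DDIT3 went from 13.8 ± 0.720 to 120 ± 16.8 CPM (log2 fold change 3.11, SE 0.0939, adjusted p = 5.32e-10). Among the largest falls were SLC1A3, INSIG1, LRRC26, RARRES2 and HAS3. INSIG1 went from 237 ± 10.6 to 50.7 ± 5.07 CPM. CDKN1A rose by 0.83 and DEGS1, a dihydroceramide desaturase (chromosome 1, 224175756 to 224193441), was at -0.70.

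All 20 DNA replication genes fell (20 adjusted over the list alone), with a median of -1.28. FEN1, a flap endonuclease (chromosome 11, 61792637 to 61797244), went from 182 ± 2.24 to 63.4 ± 1.51 CPM, PCNA, the DNA polymerase clamp, from 401 ± 9.17 to 130 ± 13.5 CPM, and MCM7 was at -0.93. The camera adjusted p was 3.54e-15, and 0.0443 with an estimated correlation. Mitosis genes fell in 15 of 18 (15 adjusted over the list alone), with BIRC5 at -1.06, AURKB at -0.87 and CCNA2 at -0.79 (camera adjusted p = 8.66e-08, and 0.0274 with an estimated correlation).

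Sterol synthesis genes fell as well. Of 21 cholesterol biosynthesis genes 19 fell, 1 rose and 1 did not pass (19 fell and 1 rose adjusted over the list alone), with a median of -0.92, HMGCS1 going from 472 ± 10.4 to 140 ± 9.95 CPM, EBP at -1.30 and DHCR7 at -1.23. The camera adjusted p was 6.08e-10, and adjusted p = 0.0562 with an estimated correlation. SCD was at -1.41, and ABCA1 did not pass (adjusted p = 0.629). Fatty acid synthesis genes fell in 13 of 19 and 1 rose (14 fell and 1 rose adjusted over the list alone, camera adjusted p = 0.000589, and 0.0274 with an estimated correlation). Sterol uptake genes fell in 9 of 13 and 2 rose (9 and 2 adjusted over the list alone, camera adjusted p = 0.00568, and adjusted p = 0.130 with an estimated correlation), and those that rose became 1 without LPDS replicate 2 or ivermectin replicate 2.

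ATF4 and integrated stress response genes rose in 26 of 29 and 1 fell (27 rose and 1 fell adjusted over the list alone), with DDIT4 at 2.51 and SESN2 at 2.29 (camera adjusted p = 2.61e-15, and 0.0274 with an estimated correlation). NF-kB and chemokine genes rose in 11 of 13 and 1 fell (12 rose and 1 fell adjusted over the list alone), with CCL20 going from 26.1 ± 1.71 to 97.0 ± 1.42 CPM, CXCL8, interleukin 8, from 34.4 ± 2.23 to 138 ± 20.9 CPM and ICAM1 at 0.78 (camera adjusted p = 6.43e-07, and 0.0274 with an estimated correlation). Nuclear-encoded respiratory chain genes fell in 22 of 26 and 1 rose (24 fell and 1 rose adjusted over the list alone), with NDUFB3 at -1.23, NDUFA2 at -1.18 and SDHA at -0.62 (camera adjusted p = 7.95e-08, and adjusted p = 0.138 with an estimated correlation). Without some single libraries the lone member moving against its list no longer passed: in the stress response list without any one LPDS library or ivermectin replicate 2 or 3, in the NF-kB list without LPDS replicate 2 or ivermectin replicate 2, and in the respiratory chain list without LPDS replicate 2. Mitochondrially encoded genes did not pass (1 of 13 lower, camera adjusted p = 0.947).

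Further lists passed camera but not with an estimated correlation: the unfolded protein response (15 rose of 20, adjusted p = 0.296 with an estimated correlation), NRF2 targets (13 rose and 3 fell of 18, adjusted p = 0.0935), heat shock (10 fell of 11, adjusted p = 0.130), Wnt targets (11 fell and 1 rose of 14, adjusted p = 0.130) and p53 targets (8 rose and 2 fell of 16, adjusted p = 0.130). Adjusted over the list alone these counts were the same. The ivermectin libraries were uneven in 2 of these lists. The mean of the unfolded protein response list, relative to the mean over 12 libraries, was 0.42, 0.72 and 0.12 in ivermectin replicates 1 to 3, with HSPA5 at 947, 1410 and 874 CPM, and that of the heat shock list -0.54, -0.24 and -0.50. Without ivermectin replicate 2, 14 unfolded protein response genes rose and 10 heat shock genes fell, and without ivermectin replicate 3 these counts were 18 and 10. Lysosome and autophagy genes, 9 higher and 3 lower of 22, did not pass camera (adjusted p = 0.0671), but passed without ivermectin replicate 2 (adjusted p = 0.0232) and with fry (adjusted p = 1.01e-06, range over the alternatives 1.01e-06 to 0.130). Against a 1.2-fold change 3340 genes passed.

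**Figure D2:**
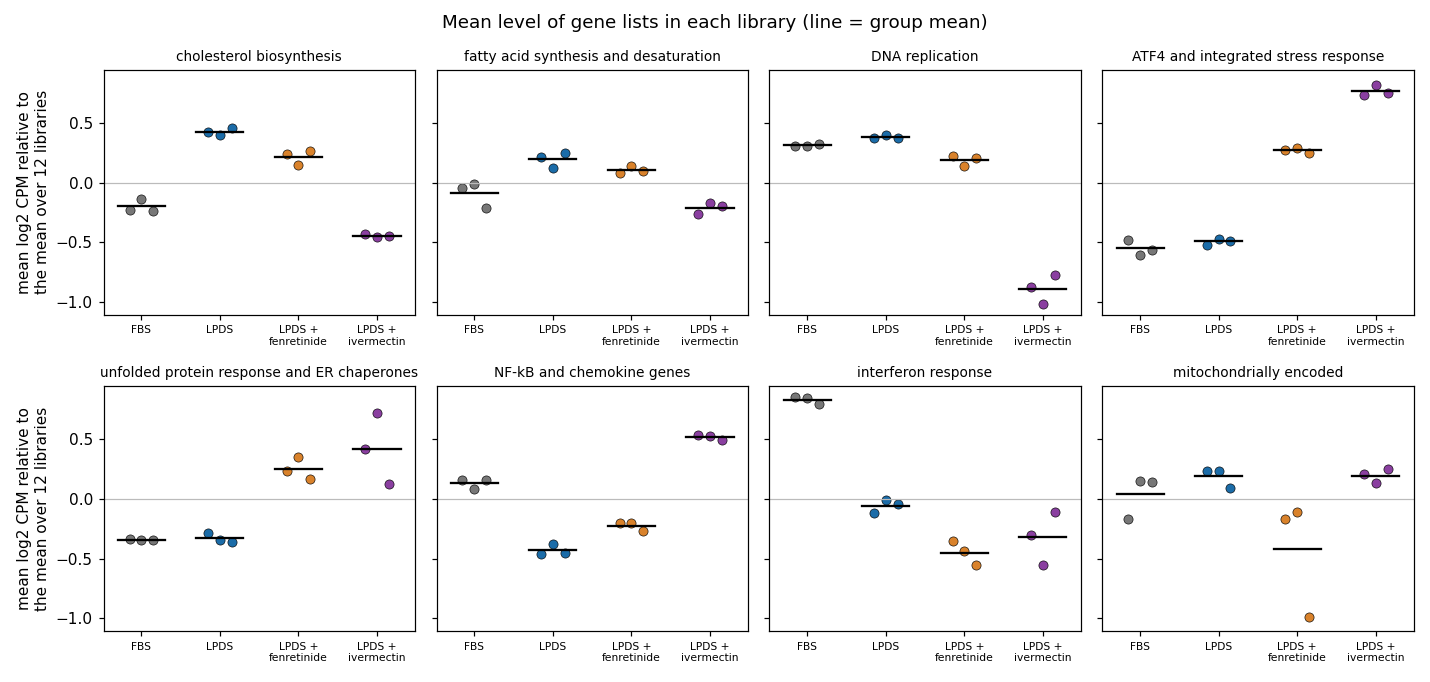
Mean log2 CPM of 8 gene lists in each library relative to the mean over 12 libraries, by group; points are libraries and lines group means. The mitochondrially encoded list in fenretinide replicate 3 lies at -0.99, below the other fenretinide libraries at -0.17 and -0.11.

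Set against each other directly, the drugs differed in 6692 genes, 3327 higher and 3365 lower with fenretinide. DNA replication genes were higher with fenretinide in 20 of 20 (20 adjusted over the list alone), with FEN1 at 1.39, PCNA at 1.56 and MCM7 at 0.78, and mitosis genes in 16 of 18 (16 adjusted over the list alone), with AURKB at 0.86, BIRC5 at 0.92 and CCNB1 at 0.55. The camera adjusted p was 8.48e-16 and 1.67e-09, and 0.0444 and 0.0406 with an estimated correlation. Cholesterol biosynthesis genes were higher in 17 of 21 and lower in 1 (17 higher and 2 lower adjusted over the list alone), with EBP at 1.16 and ACAT2 at 0.98 on the log2 scale and HMGCS1 at 2.83 times the level with ivermectin (camera adjusted p = 4.61e-08, and adjusted p = 0.0801 with an estimated correlation). Those lower became 2 without ivermectin replicate 2 or fenretinide replicate 3. INSIG1, SCD and DEGS1 were higher by 2.15, 0.82 and 0.69, and CDKN1A and ABCA1 did not pass (adjusted p = 0.783 and 0.632).

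ATF4 and integrated stress response genes were lower with fenretinide in 21 of 29 and higher in 1 (21 and 1 adjusted over the list alone), with PCK2 at -0.91, WARS at -0.92 and DDIT3 at -1.04 (camera adjusted p = 2.71e-07, and adjusted p = 0.0557 with an estimated correlation). Those higher became 2 without ivermectin replicate 3 and 0 without fenretinide replicate 1. NF-kB and chemokine genes were lower in 11 of 13 (11 adjusted over the list alone), with CCL20 at -1.38, CXCL3 at -1.41 and CXCL8 at -1.16 (camera adjusted p = 8.46e-07, and 0.0444 with an estimated correlation). Respiratory chain genes were higher in 21 of 26 and lower in 1 (22 and 2 adjusted over the list alone), with NDUFB3 at 1.02, COX6C at 0.73 and NDUFA2 at 1.00 (camera adjusted p = 1.65e-06, and adjusted p = 0.232 with an estimated correlation), and those lower became 2 without ivermectin replicate 2.

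The largest differences toward fenretinide were SNAP25, COL13A1, SLC1A3, INSIG1, PTGER2 and ANKRD1, and toward ivermectin CYP1A1, SPRR2D, LAMP3, DUOX2, SYTL1 and TXNIP. CYP1A1, a target of the aryl hydrocarbon receptor (chromosome 15, 74719542 to 74725610), was at 0.722 ± 0.121 CPM with fenretinide and 9.97 ± 0.954 CPM with ivermectin (adjusted p = 4.27e-08). TXNIP, a glucose-responsive thioredoxin inhibitor, was at 76.7 ± 4.22 and 389 ± 30.3 CPM. SNAP25 was uneven between libraries, at 8.37, 0.104 and 11.6 CPM with fenretinide and 10.7, 0.0209 and 0.172 CPM in LPDS. Its adjusted p was 0.0244, and it did not pass without ivermectin replicate 2 or 3 or fenretinide replicate 1 or 3 (adjusted p = 0.0657, 0.0580, 0.0961 and 0.101), with an offset of 5 (0.0546) or with voom (0.126), where the range over the alternatives was 0.00239 to 0.126. Hypoxia and glycolysis (9 higher and 1 lower of 16) and fatty acid synthesis genes (11 higher and 1 lower of 19) also passed camera, with an estimated correlation too (adjusted p = 0.0444 for both). Sterol uptake (10 higher and 1 lower of 13, adjusted p = 0.1003 with an estimated correlation), heat shock (10 higher of 11, adjusted p = 0.102), Wnt targets (9 higher and 2 lower of 14, adjusted p = 0.370), NRF2 targets (2 higher and 10 lower of 18, adjusted p = 0.212) and mitochondrially encoded genes (1 higher and 11 lower of 13, adjusted p = 0.614) passed camera only at the preset correlation. In these lists the counts adjusted over the list alone were the same. The mitochondrially encoded count includes fenretinide replicate 3, whose list mean relative to the mean over 12 libraries was -0.99, beside -0.17 and -0.11 in replicates 1 and 2. The 1 gene lower became 2 without fenretinide replicate 2 in the hypoxia list and without fenretinide replicate 3 in the sterol uptake list. The unfolded protein response (adjusted p = 0.193) and immediate early genes (adjusted p = 0.109) did not pass camera, but passed without ivermectin replicate 3 (adjusted p = 0.00552, range over the alternatives 0.00552 to 0.948) and without fenretinide replicate 3 (adjusted p = 0.0187, range 0.0187 to 0.686). Against a 1.2-fold change 2501 genes passed.

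**Figure D3:**
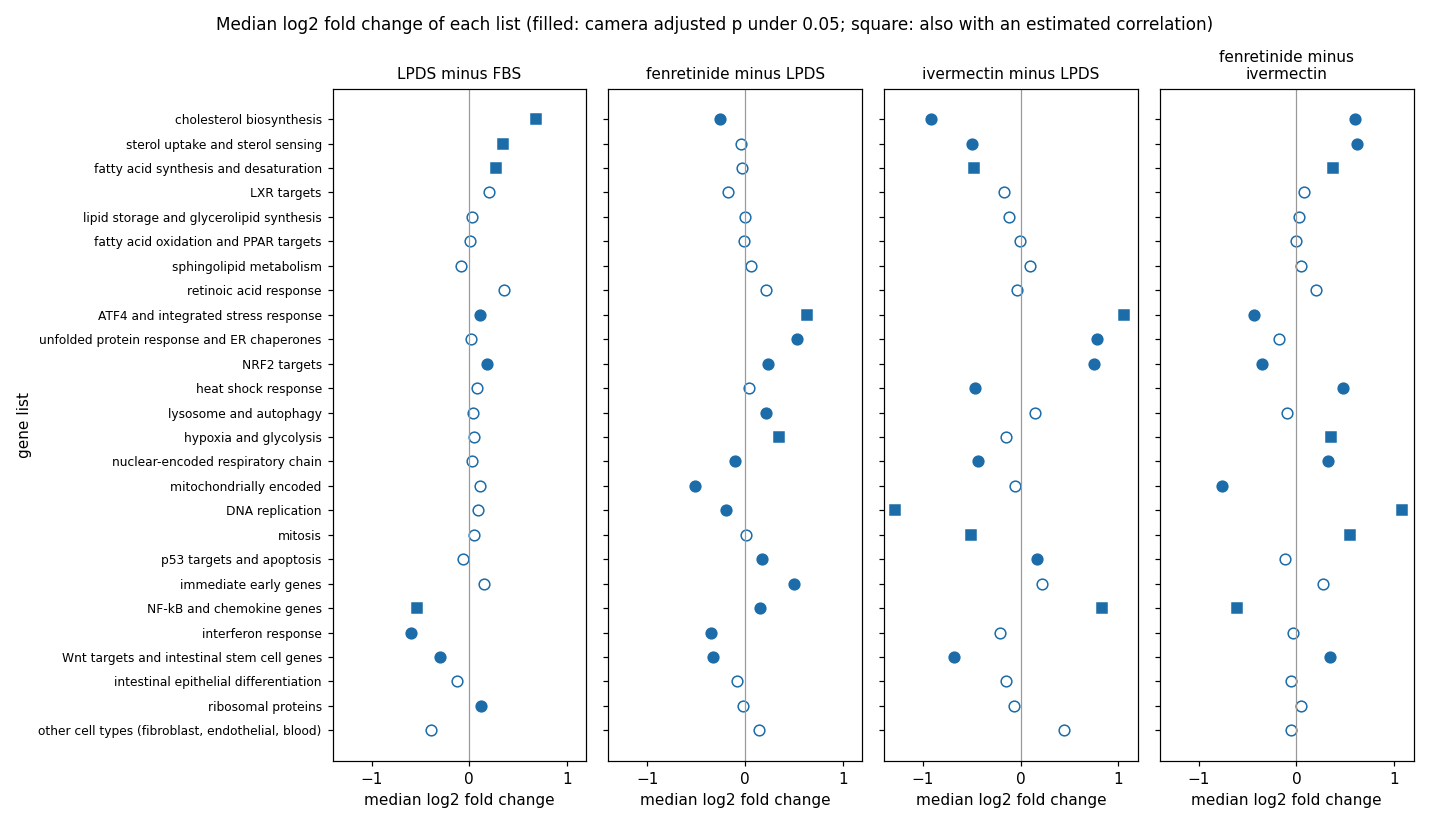
Median log2 fold change of each of 26 gene lists in 4 comparisons; filled marks passed camera at an adjusted p under 0.05 and squares also passed with an estimated correlation. DNA replication lies at -1.28 with ivermectin and -0.19 with fenretinide, relative to LPDS.

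Some lists passed camera in no comparison. Their adjusted p for medium, fenretinide, ivermectin and fenretinide against ivermectin was 0.286, 0.732, 0.756 and 0.962 for LXR targets, 0.450, 0.761, 0.681 and 0.673 for lipid storage, 0.651, 0.891, 0.947 and 0.962 for fatty acid oxidation, and 0.833, 0.332, 0.623 and 0.962 for intestinal differentiation. It was 0.117, 0.256, 0.681 and 0.663 for the 24 sphingolipid genes, which passed fry for medium, fenretinide and fenretinide against ivermectin (adjusted p = 0.0207, 0.00649 and 0.028, ranges over the alternatives 0.0207 to 0.199, 0.00649 to 0.320 and 0.028 to 0.849). In those comparisons 2, 8 and 8 sphingolipid genes were higher and 1, 5 and 5 lower. For the retinoic acid list the camera adjusted p was 0.299 for medium, 0.835 for ivermectin and 0.193 for fenretinide against ivermectin. With fry, which asks whether a list's genes move one way on average and compares them with no others, further lists passed. For ivermectin these were hypoxia (adjusted p = 0.0184, range over the alternatives 0.0184 to 0.787), immediate early genes (0.0224, range 0.0224 to 0.776) and intestinal differentiation (0.00221, range 0.00221 to 0.884). Genes moved both ways in each: 5 higher and 7 lower for hypoxia, 6 and 1 for immediate early genes, and 3 and 4 for intestinal differentiation. For fenretinide against ivermectin the lists that passed were retinoic acid response (0.000276, range 0.000276 to 0.324), p53 targets (0.00257, range 0.00257 to 0.604), lysosome and autophagy (0.0145, range 0.0145 to 0.614), intestinal differentiation (0.0257, range 0.0257 to 0.979) and immediate early genes (0.0375, range 0.0187 to 0.686). In that order the genes higher with fenretinide numbered 3, 3, 4, 3 and 7, and those lower 0, 6, 8, 4 and 1. Of 10 markers of fibroblasts, endothelium and blood, 0 were higher and 0 lower in LPDS (0 adjusted over the list alone), with a median of -0.39 and a camera adjusted p of 0.117. That list passed without FBS replicate 3 (adjusted p = 0.01, range 0.01 to 0.549), and for the other comparisons its adjusted p was 0.732, 0.523 and 0.673. The median, mean and camera direction of a list differed in sign in several lists, such as fatty acid oxidation in each comparison and sterol uptake with fenretinide, none of which passed camera.

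The drug responses overlapped in direction. Genes higher with both numbered 1071 and lower with both 929, against 420.9 and 435.5 for independent lists, while 99 rose with fenretinide and fell with ivermectin and 178 did the opposite, against 425.9 and 430.3. DDIT3, DDIT4 and SESN2 were among those higher with both. In 100 simulations of unchanged groups that share the LPDS libraries at most 1 gene was called in both. With no gene changed few are called at all, so this does not show how much overlap the shared libraries add to real responses. The correlation of log2 fold changes across genes, which are not independent replicates, was 0.445 against 0.504 in simulation, and the covariance 0.0891 against 0.0214. The simulated correlation follows from sharing LPDS with no change, so these correlations cannot be weighed against each other. With an offset of 5 the observed covariance was 0.0423, and the simulation was not repeated at that offset. Part of the excess of the counts over independent lists may come from the shared LPDS libraries. For the covariance, the simulated 0.0214 is the part that sharing gives at the fitted spread, and 0.0677 lay above it. The 277 genes in opposite directions became 161, 145 and 139 without LPDS replicates 1, 2 and 3. Nor can a solvent given with both drugs be told apart from the drugs, because the titles name no vehicle for LPDS.

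Some genes that responded to the medium also responded to ivermectin. INSIG1, SCD and HMGCS1 were among 331 genes higher in LPDS than FBS and lower with ivermectin, and CCL20 among 226 that went the other way, against 209.5 and 150.7 for independent lists. In the same direction there were 174 higher and 143 lower in both, against 207.0 and 152.5. The covariance was -0.0420 against -0.0213 in simulation, and the correlation -0.209 against -0.501. The simulated correlation follows from sharing LPDS with no change, so these correlations cannot be weighed against each other. The observed covariance was -0.0117 with an offset of 5, -0.0198 with a mean of at least 5 CPM and -0.0638 without LPDS replicate 3, on both sides of the simulated value. For fenretinide 200 genes went opposite to the medium, 110 higher in LPDS and 90 lower, against 89.8 and 63.9 for independent lists. Another 253 went with the medium, 133 higher and 120 lower in both, against 87.8 and 65.3. The covariance was -0.00457 against -0.0213. That covariance was -0.0273, -0.0111 and -0.0187 without LPDS replicates 1, 2 and 3, -0.000118 with an offset of 5 and -0.000213 with a mean of at least 5 CPM. The simulation was not repeated in any of these settings. Without LPDS replicates 1, 2 and 3 the opposite count was 368, 370 and 326 for ivermectin and 131, 114 and 101 for fenretinide, and the count in the same direction 191, 193 and 177 and 145, 128 and 128.

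The authors' deposited tables called 1276 genes for medium, 3151 for fenretinide and 7397 for ivermectin at an adjusted p under 0.05. Of these, 1226, 3063 and 7295 were also called in the same direction by the fit on log2 CPM. In the authors' deposited table DDIT3 was at 2.07 with fenretinide and 3.11 with ivermectin, FEN1 at -1.52 with ivermectin and SCD at 1.65 in LPDS. Over the 13513 genes compared, limma voom on the recovered counts, run after seeing the data, differed from those tables by at most 1.09e-05 in log2 fold change and called the 1276, 3151 and 7397 genes of the authors' deposited tables. The counts and library sizes in that run were recovered from the authors' own deposited values, so the match is not an independent check of these genes.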

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

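The log2(CPM + 1) scale and limma voom on recovered counts were chosen after seeing the data. Against a 1.2-fold change the counts of genes called fell to 300 (188 higher, 112 lower) for medium, 334 (241, 93) for fenretinide, 3340 (1614, 1726) for ivermectin and 2501 (1257, 1244) between drugs, because that test asks for more than a difference from 0. Fitting only FBS and LPDS gave 2062 (1162, 900) in place of 1320. Between drugs, fitting only the compared groups gave 5687 in place of 6692. It gave 3026 in place of 3141 for fenretinide and 7115 in place of 7370 for ivermectin. Replicates differed more within the drug groups than within FBS and LPDS, and the fit of 12 libraries shares that spread. Whether this explains the rise for medium was not tested, and a fit of fewer libraries differs in other ways too. With an estimated correlation 4, 2, 5 and 5 lists passed in place of 9, 14, 13 and 13. Leaving out 1 library, which means fewer samples, gave 813 to 984 genes for medium (484 to 578 higher, 317 to 406 lower) and 980 to 1439 lower with fenretinide. Leaving out an LPDS library gave 139 to 161 genes opposite between drugs, 326 to 370 opposite and 177 to 193 alike for ivermectin and medium, and 101 to 131 and 128 to 145 for fenretinide and medium. The other counts stayed within 1.5 times the main count. Correlations of same-numbered deviations ran from -0.0998 to 0.364, and 0 comparisons had every pair over 0.1. Between drugs they were 0.0813, 0.116 and 0.364, so with 3 replicates a batch shared by number is not excluded. A replicate block gave 1315, 3160, 7382 and 6690 genes and changed no call of a named gene or list. Direction turned only in results far from the threshold, and the cause was not tested. ABCA1 with fenretinide was at -0.00107 with an offset of 5, -0.0145 with voom and -0.20 to 0.26 over left-out libraries. Over left-out libraries DEGS1 ran from -0.040 to 0.027 for medium and -0.041 to 0.024 with fenretinide, INSIG1 from -0.17 to 0.029 with fenretinide, and CDKN1A from -0.052 to 0.13 between drugs. Lists that turned had adjusted p = 0.353 (intestinal differentiation, medium) and 0.997 (mitochondrially encoded, ivermectin) with fry, and 0.942 (sterol uptake, fenretinide) and 0.948 (intestinal differentiation, between drugs) with the block. Over left-out libraries, adjusted p for turned lists ran from 0.717 to 0.961 (unfolded protein response) and 0.745 to 0.961 (intestinal differentiation) for medium. With fenretinide it ran from 0.683 to 0.963 (sterol uptake), 0.619 to 0.963 (fatty acid oxidation) and 0.471 to 0.810 (other cell types), and with ivermectin from 0.888 to 0.970 (fatty acid oxidation) and 0.887 to 0.970 (mitochondrially encoded). Between drugs it ran from 0.868 to 0.948 (LXR targets), 0.713 to 0.973 (fatty acid oxidation), 0.814 to 0.924 (intestinal differentiation) and 0.141 to 0.948 (ribosomal proteins). Of 139 values of named genes, 14 lost their call against a 1.2-fold change. The filter at 1 CPM removed 0 genes, so testing without it says nothing. Depth limits the lowest genes, with a counting error of 16.7% at 1 CPM in the smallest library.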

Other observations

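The comparisons with FBS, the counts of list members without fenretinide replicate 3 and the splits of the libraries were tests chosen only after the results were seen. TXNIP and ARRDC4, arrestin-related genes that respond to glucose, and PRSS1 and PRSS2, trypsinogen genes that share reads, were singled out after their values were seen. TXNIP fell from 143 ± 11.3 CPM in FBS to 65.6 ± 5.32 CPM in LPDS and rose to 389 ± 30.3 CPM with ivermectin (SD, n = 3), and ARRDC4 went from 30.2 ± 2.56 to 21.4 ± 1.72 and 62.1 ± 4.49 CPM. PRSS2 was at 72.8 ± 11.4 CPM in FBS, 160 ± 9.97 in LPDS and 853 ± 25.0 with ivermectin, and PRSS1 at 9.60 ± 1.26, 19.9 ± 1.54 and 117 ± 4.61 CPM. With fenretinide TXNIP did not pass against LPDS (adjusted p = 0.0548).

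The drug groups were also set against FBS. With ivermectin HMGCS1, DHCR7 and INSIG1 were below FBS (log2 fold change -0.55, -0.27 and -0.61), and with fenretinide they were above it, by 0.95, 0.59 and 1.54. Not all lipid genes fell below FBS with ivermectin: SCD did not pass (0.24, adjusted p = 0.0675) and SREBF1 was above it by 0.20. Against FBS, 5 sterol uptake genes were higher and 4 lower of 13 (camera adjusted p = 0.968). Of 19 fatty acid synthesis genes 2 were higher and 7 lower (camera adjusted p = 0.297).

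Cholesterol biosynthesis genes were lower with ivermectin than in LPDS. A return to the level in FBS medium was tested: 13 of the 21 genes differed between ivermectin and FBS, 11 lower and 2 higher. Those genes were not at the FBS level. Ivermectin changed 54.5% of all genes tested against LPDS, and the share of all genes that differed from FBS is not given here. Many genes of any list may therefore differ from FBS, and the count does not decide whether a return explains the fall of the list. The list median against FBS was -0.19, beside -0.92 against LPDS, with a camera adjusted p of 0.0106, and adjusted p = 0.377 with an estimated correlation. Other causes of the fall were not tested.

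Mitochondrially encoded genes were lower with fenretinide, most of all in replicate 3. To ask whether fenretinide replicate 3 alone carried the pattern, it was left out. Then 5 members were still lower, MT-CO1, MT-CO3, MT-ATP6, MT-ATP8 and MT-CYB, at -0.43, -0.73, -0.71, -0.71 and -0.40, which argues against that library as the whole cause for these genes. The other 8 members were at -0.11 to -0.23 and did not pass, which leaves open how much of their fall came from that library. RNA handling in that library was not tested and stays open beside a drug effect. Against FBS, with every fenretinide library included, 5 of 13 members were lower (camera adjusted p = 0.0087, and adjusted p = 0.598 with an estimated correlation). In that comparison MT-CO3 was lower (-0.72, adjusted p = 0.00581), and MT-ATP6 and MT-ATP8 did not pass (adjusted p = 0.0858 and 0.0794).

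Other splits of the 6 libraries in each comparison are too few to give a share under 0.05, since there are 10. The real split was the 1 split with as many genes in each: 1320 genes for medium, 7370 for ivermectin and 6692 between drugs, where the highest other split called 0, and 3141 for fenretinide, where the highest other called 55.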
